A study of Drosophila melanogaster with 32 samples.

How the data were processed

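ChIP-seq peak lists of 24 libraries from Drosophila melanogaster Kc167 cells were analysed. They came from 12 groups of 2 libraries, for antibodies against M1BP, CP190, Su(Hw) and Mod(mdg4) in mock-treated cells and cells with M1BP knockdown, and for M1BP and CP190 in a second mock set and cells with CP190 knockdown. Per the labels, cells were transfected with 20 µg of double-stranded RNA against M1BP or 12 µg against Cp190 and kept for 5 days. A further 8 input libraries of the 32 had no list and were not analysed here. The remaining protein or transcript of either target was not measured in the data used here.

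Per the submitters' processing notes, Bowtie2 2.3.5, SAMtools 1.9, Picard 2.20.2 and MACS2 2.2.5 were used. The order and options of these steps are not given in the sources used here. Peaks were called by the authors for each library on its own, as the peak names show. The deposited score of a peak is the integer that MACS2 writes, 10 times its -log10 q rounded down, and was not used in tests. The fold enrichment of a peak is the ratio of ChIP to control signal that the authors' peak caller gave, and it is not scaled between libraries. The -log10 p and -log10 q of a peak are those that the authors' peak caller gave. The other deposited value is the position of the summit in bp from the peak start. The smallest -log10 q was 1.30, a threshold of q = 0.05. In 19 of the 24 lists the numbering of peaks skipped some numbers, at most 7 in a list and 33 in all. Fold values served only to describe, rank and filter peaks within a list.

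The genome build is not given in the labels. The sequence names, and a largest chrM coordinate of 19524, match dm6, and positions are printed as in the deposited lists. A gene table of that assembly was used for names, neighbouring genes, gene ends and the tests of gene lists. It held 17673 genes on the chromosome arms, without strand, so promoter tests were replaced by gene ends. A gene-end site has its summit within 250 bp of either end of an annotated gene, and takes the name of the nearest one. No genome sequence was used here, and the planned search for motifs at the sites was not run. Of all peaks 611 (0.541%) lay off the arms 2L, 2R, 3L, 3R, 4 and X. They were kept in counts of sites and left out of circular shifts and gene-end tests.

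For each antibody and knockdown, peaks of the 4 lists that overlapped by at least 1 bp were merged into sites. Sites were classed as lost, retained or gained as the results define them, and other sites were left unclassed. A lost site has no peak past the authors' threshold, which is not the same as no binding. Each count was set beside the same count under the 2 crossed groupings of the 4 libraries, in which each side holds a control and a knockdown library. Loss was compared by overlap with sites of the other protein bound in both control libraries, with Fisher's exact test, two-sided, and an exact 95% interval of the odds ratio. Benjamini-Hochberg adjustment ran over the 7 tests of loss and gain, and an adjusted p under 0.05 passed. A Woolf test compared odds ratios where each cell held at least 10 sites. The share of M1BP sites overlapping each insulator protein was set against 10000 circular shifts along each arm, one-sided, a permutation test whose smallest p is 1e-04. Percentile ranks of fold enrichment among retained sites were compared with 100000 permutations, two-sided, whose smallest p is 1e-05. Peak numbers were compared by exact permutation of libraries, where 2 against 2 cannot go below p = 0.333. Shares carry 95% Wilson intervals.

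The labels do not say whether replicates are separate cultures, so a p from libraries measures the spread between these samples, which may be technical. Sites are not replicates, and tests across sites describe these libraries. Intervals cover counting error only. Read depth per library is not given in the sources used here, and the 1699 to 8443 peaks per list limit the precision.

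The 10 gene lists hold ribosomal protein (92 genes matched), mitochondrial respiratory chain (86), proteasome (45), translation initiation factor (44), replication licensing (16), heat shock (23), homeotic (8), insulator protein (16), histone (115) and cell cycle genes (19). The names lat and Z4 matched no gene, and histone genes are repeated in the genome, so their sites are uncertain. Members were tested against other gene-end sites by Fisher's exact test, two-sided, with adjustment over the lists of a comparison. Named genes follow a rule. It takes the 8 lost, 5 retained and 5 gained gene-end sites of each comparison with the highest mean fold enrichment, up to 4 members of each list with the highest mean control fold enrichment, and the M1BP and Cp190 loci. Not every gene that this rule picks is reported here. Groups, tests, lists, the naming rule (with transcription start sites in place of gene ends) and the following alternatives were chosen before the data were examined. These were summits within 100 bp, overlap of at least 50% of each site, peaks of -log10 q of 10 or more, lists of equal length, 5 strata of control strength, a replicate block, ranks by -log10 p, the second mock set, and leaving out each library in turn. Alternatives with gene ends or chromosome arms, and those for the gene list, the Woolf test, the named sites and the peak numbers, were chosen after seeing the data.

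The procedure was tested on simulated data made by planting 200 losses and up to 193 gains among the sites of each comparison. It recovered 89.5 to 95% of the losses and 87.6 to 96.1% of the gains, with at most 18 false losses and 16 false gains. In the simulation each list missed few sites, independently of the others, and losses were complete, so these rates largely follow from that setting. Real replicate lists agreed less, down to 50.3% of sites shared for Mod(mdg4), so the rates are not the error on these data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.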

Results

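Chromatin immunoprecipitation with sequencing (ChIP-seq), which maps where a protein sits on chromatin, was done in Kc167 cells, an embryo-derived cell line of Drosophila melanogaster. The antibodies were against M1BP, a zinc-finger protein that binds the Motif 1 element of promoters, and against the insulator proteins CP190, Su(Hw) and Mod(mdg4). In the first experiment all 4 proteins were mapped in mock-treated cells and in cells given double-stranded RNA against M1BP. In the second experiment M1BP and CP190 were mapped in a separate set of mock-treated cells and in cells given double-stranded RNA against Cp190. Each of the 12 combinations of antibody and treatment had 2 libraries, which makes 24 peak lists. A further 8 input libraries had no list and were not analysed here. The lists held 113005 peaks, from 1699 to 8443 per library, and the read depth behind them is not given in the sources used here.

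Each knocked-down protein had fewer peaks in both of its knockdown libraries than in either mock library. M1BP had 2880.5 ± 141 peaks per library in mock cells and 1737.5 ± 54.4 after M1BP knockdown (mean ± SD, n = 2 libraries each), a change of -39.7%. CP190 had 8320 ± 174 peaks in the second mock set and 2090.5 ± 84.1 after CP190 knockdown, a change of -74.9%. After M1BP knockdown the number of CP190 peaks was 7895 ± 281 against 7813.5 ± 24.7, that of Su(Hw) peaks 5450.5 ± 179 against 4561.5 ± 24.7, and that of Mod(mdg4) peaks 5218.5 ± 504 against 3331.5 ± 470. M1BP peaks after CP190 knockdown numbered 3568.5 ± 81.3 against 3635 ± 296. The exact permutation test, two-sided, gave p = 0.333 for M1BP and CP190 after their own knockdown and for Su(Hw) and Mod(mdg4), the smallest p that 2 libraries against 2 allow. The same exact test gave p = 1 for CP190 after M1BP knockdown and for M1BP after CP190 knockdown, where the control and knockdown libraries overlapped.

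**Figure D1:**
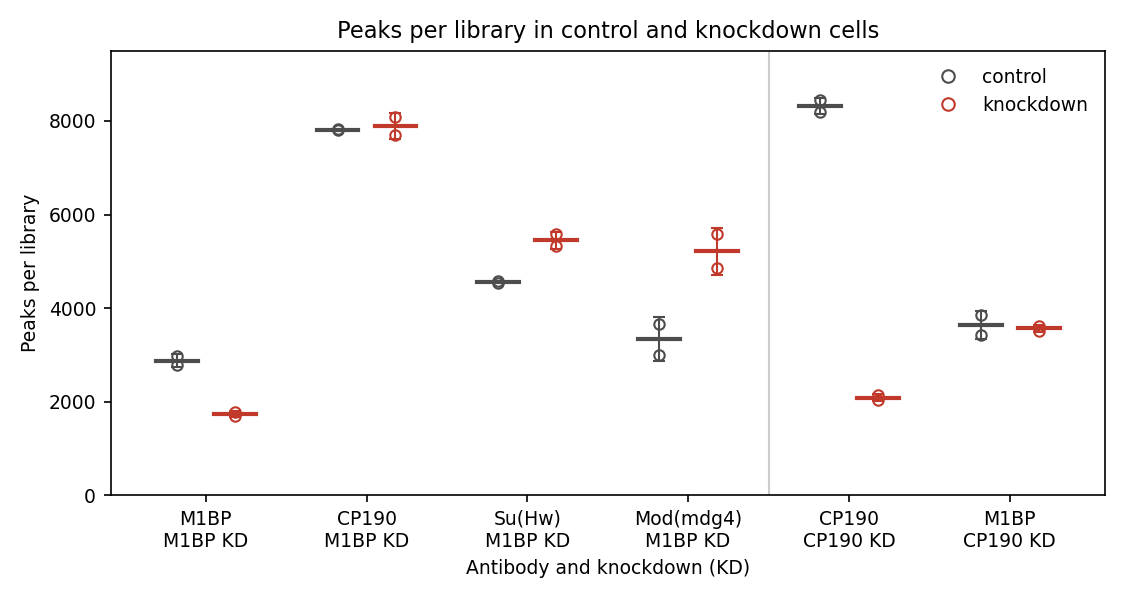
Number of peaks per library (vertical axis) for each antibody and knockdown (KD, horizontal axis); open circles are the 2 libraries of a group, thick lines their mean and whiskers 1 SD, with control in grey and knockdown in red. Under their own knockdown M1BP lists had a mean of 1737.5 peaks against 2880.5 and CP190 lists 2090.5 against 8320, and both Mod(mdg4) knockdown lists lay above both control lists.

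Replicate lists shared 79.5 to 82.0% of their sites for M1BP, 73.3 to 89.4% for CP190, 87.3 to 91.2% for Su(Hw) and 50.3 to 71.3% for Mod(mdg4). The mock lists of the 2 experiments shared 85.3 to 87.1% for CP190 and 60.8 to 66.7% for M1BP. Each knockdown was therefore compared with the mock libraries of its own experiment. A site is called lost here when it had a peak in both control lists and in neither knockdown list, retained when it had a peak in all 4 lists, and gained when it had a peak in both knockdown lists and in neither control list.

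How far M1BP coincides with the insulator proteins in mock cells is a question the design names. M1BP sat at gene ends, with 2020 of its 2516 sites on chromosome arms (80.3%) within 250 bp of an annotated gene end at a median distance of 30 bp. CP190 had 50.9% of its 7227 sites there, Mod(mdg4) 16.7% of 2693 and Su(Hw) 11.8% of 4296. Of the 2516 M1BP sites, 1971 (78.3%, 95% Wilson interval 76.7 to 79.9) overlapped a CP190 site, 4.17% (3.46 to 5.03) a Mod(mdg4) site and 101 (4.01%, 3.31 to 4.85) a Su(Hw) site. Of all 2526 M1BP sites, those off the arms included, 73.6% had CP190 as the sole partner, 3.33% had all 3 insulator proteins and 21.3% had none of them. Circular shifts of the partner sites along each chromosome arm gave a mean overlap of 9.28% for CP190, so the overlap was 8.45-fold higher (one-sided permutation p = 1e-04, the smallest the shifts can give), and 21.4-fold with at least 50% of each site overlapping or 44.2-fold with summits within 100 bp. The shifts do not keep sites at gene ends, where M1BP and CP190 both lay often, so these folds include any excess from that shared location. Among gene ends CP190 kept its direction and passed. For Mod(mdg4) the overlap was 1.3-fold that of the shifts (one-sided permutation p = 0.0072, adjusted p = 0.0108 over the 3 partners). That call was lost with peaks of -log10 q of 10 or more (1.11-fold, permutation p = 0.239), and among gene ends the odds ratio was 0.758. The overlap was 2.2-fold when at least 50% of each site had to overlap and 2.99-fold with summits within 100 bp (permutation p = 1e-04 for both). For Su(Hw) it was 0.685-fold (permutation p = 1 for as many or more, and p = 1e-04 for as few or fewer), and the direction turned, at 1.62-fold, when summits within 100 bp were required. In the second mock set 86.8% of M1BP sites overlapped a CP190 site, 8.82-fold over the shifts.

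After M1BP knockdown, M1BP itself was lost at 894 of the 2526 sites bound in both mock libraries (35.4%, 95% Wilson interval 33.6 to 37.3), and retained at 1468. The lost gene-end sites with the highest fold enrichment in mock cells were at HemK1 (2L, 6467193 to 6468153, folds of 37.9 and 30.1 in the 2 mock libraries), at cdm (3R, 18183040 to 18184188, 29.4 and 33.1), at CG5026 (30.4 and 31.2) and at Dolk, which encodes dolichol kinase (29.5 and 30.2). Rab23, a small GTPase, lost its site with folds of 30.8 and 26.1. The site shared by alphaSnap, a factor of vesicle fusion, and polo, a mitotic kinase, was lost too (28.4 and 20.2). Sites at CG3777 and ewg (25.1 and 21.4) and at tth (23.9 and 21.3) complete the 8. Among retained gene-end sites the highest mock folds were at Mpcp2, a mitochondrial phosphate carrier (3L, 14537237 to 14538086, 52.3 and 36.9 in mock and 11.0 and 21.5 in knockdown libraries), and at wds (43.2 and 42.5 in mock, 6.08 and 11.9 in knockdown). Next came CG8516 (43.2 and 36.5, then 15.0 and 25.9), CG17721 and Arfip (36.9 and 42.7, then 3.61 and 6.50) and eas, an ethanolamine kinase gene (38.9 and 40.3, then 18.6 and 26.8). Retained means a peak in all 4 lists and not an unchanged fold, and folds are not scaled between libraries. The 28 gained sites included Tcs5 (3.82 and 4.41 in the knockdown libraries), fws (3.12 and 4.46), lncRNA:CR44478, moody and Gapdh2, a glycolytic enzyme gene (2.73 and 3.65).

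Loss followed peak strength. It took 70.8% of the weakest quintile of M1BP sites by rank of mock fold enrichment, 66.9%, 26.5% and 10.1% of the next ones, and 2.57% of the strongest. Lost sites had a median control rank of 24.4% and retained sites of 67.8%, where 100 is the strongest. Gene ends held 68.3% of lost and 88.4% of retained sites. Crossed groupings of the same 4 libraries, which mix control with knockdown, gave at most 25 sites, against 894 lost and 28 gained. For the lost sites this count says little about replicate differences. The knockdown lists were short, and 91.4 to 94.7% of their peaks lay in each mock list, which keeps crossed counts low. The 28 gained sites rose to 56 without mock replicate 1, to 74 without knockdown replicate 1 and to 98 without knockdown replicate 2. With lists of equal length 275 sites were lost and 203 gained.

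Among ribosomal protein genes, 8 of 50 gene-end M1BP sites were lost (16.0%, against 30.6% of other gene-end sites) and 39 were retained, RpL37A (42.5 and 30.0 in mock) and RpL3 (36.5 and 27.3) among them. Respiratory chain genes lost 4 of 31 sites (12.9%), and ND-PDSW (37.5 and 38.6 in mock, 10.2 and 14.8 in knockdown), UQCR-C2 (38.7 and 35.9, then 8.38 and 11.9) and SdhB (36.0 and 34.1, then 5.56 and 6.15) were retained. For the other list genes here the folds are those of mock cells. Fisher's exact tests, two-sided, gave p = 0.0283 for the ribosomal protein and p = 0.0464 for the respiratory chain genes, and both had an adjusted p of 0.209, so neither passed. Proteasome genes lost 5 of 19 sites, with Rpt4 retained (31.5 and 36.2), and translation initiation factor genes 4 of 15, with eIF3k retained (37.9 and 36.5). Replication licensing genes lost 1 of 5, with Mcm6 retained (12.4 and 12.3), and heat shock genes 0 of 3, with Hsc70-4 retained (27.7 and 23.5). Cell cycle genes lost 4 of 11, with polo lost and Rbf retained (31.7 and 32.3). Histone genes lost His3.3A (15.0 and 13.6) and retained His4r (24.3 and 20.0). Insulator protein genes lost 3 of 6, mod(mdg4) among them (11.0 and 7.25), and retained ZIPIC, Clamp and Chro. No homeotic gene had a gene-end M1BP site bound in both mock libraries. At the Cp190 gene a weak M1BP site was lost (3R, 15274958 to 15275719, 3.40 and 3.25), and the M1BP gene had no M1BP site.

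**Figure D2:**
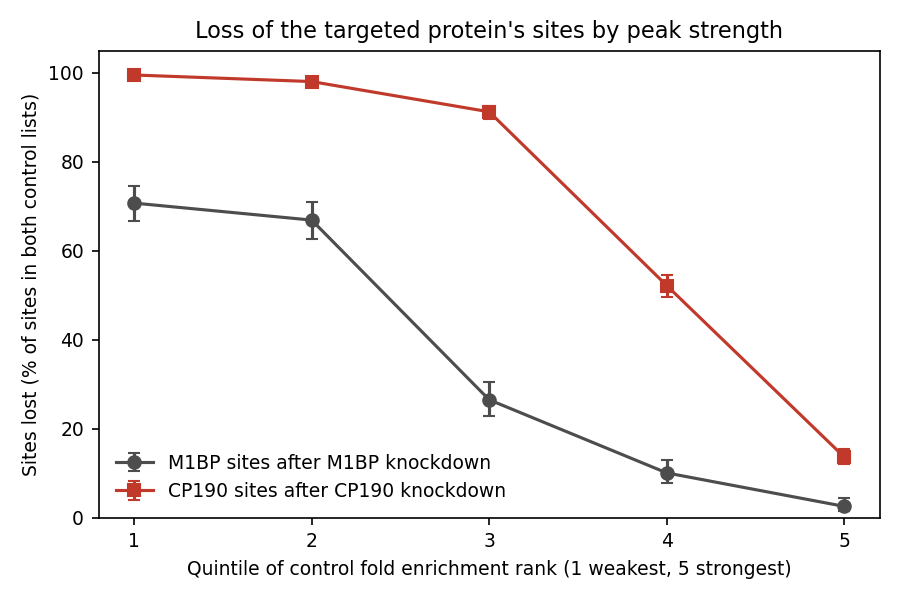
Percent of sites bound in both control libraries that had no peak in either knockdown library (vertical axis), by quintile of the rank of control fold enrichment (horizontal axis, 1 weakest, 5 strongest); points are the percent over all sites of a quintile and whiskers its 95% Wilson interval. M1BP loss after M1BP knockdown (grey) went from 70.8% to 2.57% and CP190 loss after CP190 knockdown (red) from 99.6% to 13.7%.

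CP190 kept most of its sites after M1BP knockdown and lost more of those it shared with M1BP. Of the 7168 sites bound in both mock libraries 305 were lost (4.26%, 95% Wilson interval 3.81 to 4.75) and 6601 were retained, and 317 sites were gained. Among CP190 sites that overlapped an M1BP site, 176 of 1994 were lost (8.83%, 7.66 to 10.2), against 129 of 5174 elsewhere (2.49%, 2.10 to 2.95). Lost sites that M1BP also bound in mock cells lay at CG17721 and Arfip (3R, 11234797 to 11235620, 10.3 and 13.0), at Nthl1, which encodes a DNA repair glycosylase (2L, 20927279 to 20928125, 10.6 and 9.20), at CG2218 (9.30 and 9.85), at CG7755 (8.60 and 8.73) and at Nse1, a gene of the Smc5/6 complex (6.83 and 8.97). At lncRNA:CR45639 (3R, 16206957 to 16208515, 16.8 and 18.0), veil (10.4 and 9.25) and CG17717 (8.92 and 10.2) CP190 was lost at sites without M1BP. Among retained gene-end CP190 sites the highest mock folds were at Atet (59.4 and 62.3 in mock), bcd, the anterior morphogen gene (60.3 and 60.8), dnc, a cyclic AMP phosphodiesterase gene (54.7 and 48.6), CG6465 (57.8 and 40.9) and CR31958 (55.1 and 43.3), none of them at an M1BP site. Gained sites lay at CG32170 (11.3 and 12.4 in knockdown), Mmp1, a matrix metalloproteinase gene (7.71 and 9.02), RpS5b (6.55 and 8.0), Cyp6v1 (7.09 and 6.66) and CG7054 (6.38 and 7.27), the last of which M1BP bound in mock cells.

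The odds ratio of CP190 loss at M1BP sites was 3.79 (95% interval 2.98 to 4.82, Fisher's exact test, two-sided, adjusted p = 2.06e-28 over 7 tests). It was 2.40 without mock replicate 2 and 2.27 without knockdown replicate 1, and 6.53 (4.31 to 10.2) among gene-end sites. The replicate block, reported below with the alternatives, gave a lower value than these. The sites elsewhere included 2255 with both Su(Hw) and Mod(mdg4), of which 6 were lost. They also included 2342 with none of the other 3 proteins, of which 102 were lost (4.36%). Of gained CP190 sites 7.26% lay at M1BP sites, against 27.8% of sites bound in both mock libraries (odds ratio 0.203, 0.126 to 0.312, Fisher's exact test, adjusted p = 4.52e-19), and the odds ratio was 0.341 with peaks of -log10 q of 10 or more. This gap does not show that gains avoided M1BP. A site bound by CP190 in mock cells cannot be gained, and 78.3% of M1BP sites on the arms overlapped such a site. Lost CP190 sites had a median control rank of 14.3% and retained ones of 53.1%. Crossed groupings gave at most 81 sites. The lost count was 485 without mock replicate 1, 496 without mock replicate 2 and 517 without knockdown replicate 1, and the gained count 524, 502 and, without knockdown replicate 2, 616.

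No ribosomal protein gene lost CP190 after M1BP knockdown (0 of 64 gene-end sites, against 4.84% of other gene-end sites, Fisher's exact p = 0.0737, adjusted p = 0.664), and RpS15Aa (38.0 and 38.2), RpS14a (31.7 and 40.4) and RpL17 (30.2 and 39.1) were retained. Respiratory chain genes lost 2 of 51 sites and proteasome genes 2 of 23, with ATPsynC (32.6 and 35.8), ND-B8 (34.6 and 31.7) and Prosbeta2R2 (24.9 and 28.8) retained. Translation initiation factor genes lost 0 of 25, replication licensing genes 0 of 12, histone genes 0 of 4 and cell cycle genes 0 of 15. The retained ones included eIF4G2 (35.6 and 27.9), Orc4 (29.4 and 21.9), His2Av (16.5 and 26.2) and stg, the Cdc25 phosphatase gene (33.4 and 36.2). Heat shock genes lost 1 of 8 and insulator protein genes 1 of 10, with DnaJ-1 (35.9 and 27.8), CTCF (29.0 and 28.3) and pita (18.3 and 26.1) retained. None of these lists passed the test. CP190 stayed at the Cp190 gene (5.18 and 3.19 in mock, 5.07 and 3.81 in knockdown), and at the M1BP gene it had 1 peak, in mock replicate 1 alone (2.59).

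Su(Hw) kept nearly all of its sites after M1BP knockdown. Of 4215 sites bound in both mock libraries 18 were lost (0.427%, 95% Wilson interval 0.270 to 0.674), 4173 were retained and 553 were gained. The single lost site at a gene end lay at Mpcp2 (3L, 14537309 to 14537673, 3.31 and 3.04), where M1BP had its strongest retained gene-end site by mean mock fold. At least 1 of its mock peaks had a -log10 q under 10. Retained sites included CG5386 (31.1 and 36.6), dbf (24.7 and 39.7), CG11380 (31.8 and 32.1), ppk23, an ion channel gene (24.1 and 33.6), and the odorant receptor gene Or43a (30.9 and 25.7). Gained sites lay at CG32170 (3L, 16879114 to 16879837, 9.69 and 11.4 in knockdown), at Mbs, which encodes the binding subunit of myosin phosphatase (6.55 and 6.38), at CG11672 (5.42 and 5.87), at mirr, a homeodomain gene (4.35 and 5.88), and at Osi23 (4.55 and 4.97). M1BP bound the Mbs site in mock cells. Few genes of the fixed lists had a gene-end Su(Hw) site and none of these was lost, as at RpL28 (8.68 and 9.16), SdhC (12.3 and 13.6), ND-B17 (7.03 and 8.65), Rpn13 (5.23 and 6.92), eIF4E5 (12.2 and 14.7) and eIF2gamma (6.17 and 6.07).

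Loss of Su(Hw) was more frequent at M1BP sites, with 7 of 120 lost (5.83%, 2.85 to 11.6) against 11 of 4095 (0.269%, 0.150 to 0.480). The odds ratio was 22.9 (7.39 to 66.2, Fisher's exact test, two-sided, adjusted p = 4.37e-07). It was 116 with peaks of -log10 q of 10 or more, 11.0 with summits within 100 bp and 5.55 with lists of equal length. Among gene-end sites 1 of 34 was lost at M1BP sites and 0 of 469 elsewhere, which did not pass (Fisher's exact p = 0.0676). The odds ratio was 14.8 without mock replicate 1, 5.76 without mock replicate 2 and 11.9 without knockdown replicate 1. Lost Su(Hw) sites were weak, with a median control rank of 3.12% against 50.9% for retained sites, and dropout between the mock lists was not tested for Su(Hw). The 18 lost sites did not exceed the 21 sites of the largest crossed grouping, and became 34 without mock replicate 1, 58 without mock replicate 2, and 29 and 31 without knockdown replicates 1 and 2. The 553 gained sites were above that grouping, and numbered 1042 without knockdown replicate 2. That grouping is no measure for gains, since 98.0 to 98.7% of mock peaks lay in each knockdown list, which keeps crossed counts low. With lists of equal length 84 sites were lost and 175 gained. Gained sites were not detectably more frequent at M1BP sites (odds ratio 1.48, 0.896 to 2.35, Fisher's exact test, adjusted p = 0.128).

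Mod(mdg4) was lost at 104 of 2685 sites after M1BP knockdown (3.87%, 95% Wilson interval 3.21 to 4.67), was retained at 2420 and gained 552. Of these gained sites 509 lay on the chromosome arms. Peaks off the arms made up 2.03 and 3.66% of the Mod(mdg4) knockdown lists, against 0.90 and 0.60% of the mock lists. Lost gene-end sites lay between miniature (m) and dusky (dy), genes of wing shape (X, 11769367 to 11769869, 5.73 and 6.54), at CG12725 (6.49 and 5.16), at Galphaf, a G protein subunit gene (3L, 16662051 to 16662830, 4.94 and 4.81), at kek5 (4.23 and 5.25), at CG43693 (3.92 and 5.18), at Got2, an aspartate aminotransferase gene (3.97 and 4.72), at MCTS1 (4.11 and 4.36) and at the tyrosine kinase gene Btk (3.56 and 4.37). Of these 8, the Galphaf site overlapped an M1BP site, and 1 of the 8 stayed lost when peaks of -log10 q of 10 or more were required. Retained sites included dbf (23.8 and 38.3), Lapsyn (29.8 and 27.7), Neto (24.2 and 30.5), CG32812 (28.9 and 23.1) and dnc (27.0 and 24.8). Gained sites lay at Mbs (3L, 16051755 to 16052304, 7.15 and 6.78) and CG11672 (6.39 and 4.66), which gained Su(Hw) as well, and at E23 (6.85 and 4.04), CG15200 (4.51 and 5.14) and sog, a gene for a BMP antagonist (5.59 and 3.10). The few list genes with a gene-end Mod(mdg4) site lost none, as at SdhC (14.1 and 15.6), ND-B17 (6.80 and 8.71), Rpn13 (6.31 and 7.25) and eIF4E5 (13.4 and 14.7).

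At M1BP sites 18 of 118 Mod(mdg4) sites were lost (15.3%, 9.87 to 22.8), against 86 of 2567 elsewhere (3.35%, 2.72 to 4.12). The odds ratio was 5.19 (2.82 to 9.10, Fisher's exact test, two-sided, adjusted p = 4.37e-07). It was 25.6 (12.2 to 53.0) with peaks of -log10 q of 10 or more, 1.92 without mock replicate 1 and 3.42 without mock replicate 2, and among gene-end sites it was 2.60 and did not pass (Fisher's exact test, adjusted p = 0.128). For gained sites the odds ratio at M1BP sites was 0.989 (0.603 to 1.56, Fisher's exact test, adjusted p = 1), but 2.08 with lists of equal length (1.07 to 3.75, Fisher's exact test, adjusted p = 0.0217). Lost Mod(mdg4) sites had a median control rank of 11.6% and retained ones of 55.0%, and dropout between the mock lists was not tested for Mod(mdg4). Mod(mdg4) lists differed most between replicates, and a crossed grouping gave 189 sites, more than the 104 lost and fewer than the 552 gained. With lists of equal length the balance turned, to 223 lost and 159 gained. Lost counts were 376 without mock replicate 1, 204 without mock replicate 2 and 250 without knockdown replicate 1. Gained counts were 930 without mock replicate 2, 1806 without knockdown replicate 1 and 2230 without knockdown replicate 2.

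**Figure D3:**
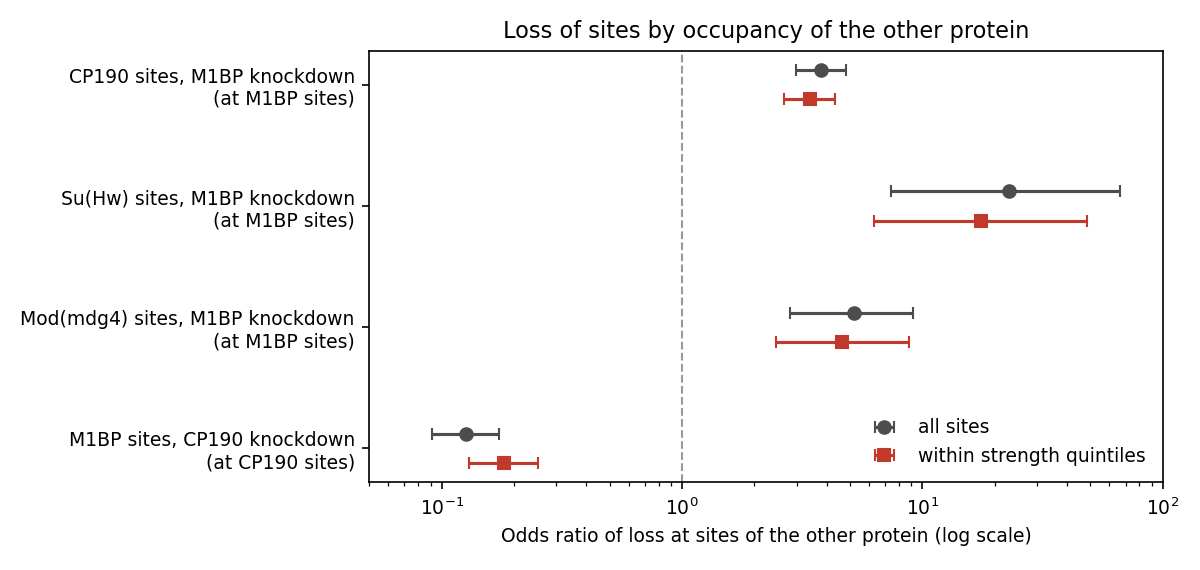
Odds ratio of losing a site when the other protein was bound there in control cells (horizontal axis, log scale), for each antibody and knockdown (vertical axis); grey circles are all sites, red squares the common value within quintiles of control peak strength, whiskers 95% intervals and the dashed line an odds ratio of 1. CP190 (3.79), Su(Hw) (22.9) and Mod(mdg4) (5.19) lie above 1 at M1BP sites, and M1BP lies below 1 at CP190 sites (0.126).

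The odds ratio of CP190 loss at M1BP sites, divided by that of Mod(mdg4), was 0.729, and the 95% interval of the Woolf test, two-sided, held 1 (0.403 to 1.32). With peaks of -log10 q of 10 or more the same ratio was 0.144 (0.0697 to 0.296), below 1. Pairs with Su(Hw) were not tested, since 7 lost sites are under the 10 per cell set for the test. Among sites retained in all 4 lists, those at M1BP sites moved down in rank after M1BP knockdown relative to other sites, by -3.21 percentile points for CP190 and -8.56 for Mod(mdg4). Permutation tests, two-sided, gave p = 1e-05 for CP190, the smallest they can give, and p = 2e-05 for Mod(mdg4). For Su(Hw) the difference was -3.61 (permutation p = 0.00505), but it was -1.72 with ranks by -log10 p (permutation p = 0.0904) and 1.78 with summits within 100 bp (permutation p = 0.533). The same difference taken site by site between replicate 1 and replicate 2 was -0.74 in mock and -1.20 in knockdown libraries for CP190, -1.98 and -1.34 for Su(Hw), and 0.29 and 0.08 for Mod(mdg4). The median percentile of M1BP-bound sites in single libraries was 45.0 and 45.2 in mock and 41.4 and 43.0 in knockdown cells for CP190, and 59.1 and 53.9 against 51.2 and 51.5 for Mod(mdg4). For Su(Hw) the knockdown libraries, at 39.5 and 40.9, lay between the mock libraries, at 37.8 and 43.9.

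After CP190 knockdown CP190 was lost at most of its sites. Of 7788 sites bound in both mock libraries of the second experiment 5526 were lost (71%, 95% Wilson interval 69.9 to 72.0) and 1729 were retained. Lost gene-end sites lay at Syn2, a syntrophin gene (2R, 16551542 to 16552655, 38.9 and 36.3 in mock), at CG15025 (3R, 19490590 to 19491620, 45.5 and 26.0), at CG3703 (35.8 and 32.1), at CG9030 (33.7 and 32.6), at CG15554 (38.4 and 27.3), at CG43181 (33.2 and 29.9), at a threonine tRNA gene on 2R (28.9 and 30.9) and at CG17450 (30.1 and 28.9). Among retained gene-end sites the highest mock folds were at ct, a homeodomain gene (X, 7678585 to 7679958, 62.5 and 34.9 in mock, 24.4 and 20.0 in knockdown), CR31958 (46.8 and 48.7, then 8.93 and 12.1) and fal (46.3 and 47.4, then 14.7 and 14.1). Atet (53.1 and 40.3, then 22.6 and 24.7) and bcd (56.0 and 36.1, then 14.5 and 14.4) followed. At CR31958, Atet and bcd CP190 was also retained after M1BP knockdown. CP190 was lost from the Cp190 gene (3R, 15274864 to 15275693, 5.10 and 5.47). No gained site lay at a gene end.

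Loss of CP190 took 99.6% of the weakest quintile of its sites, 98.1%, 91.3% and 52.2% of the next ones and 13.7% of the strongest. The median control rank was 35.7% for lost and 86.9% for retained sites. Crossed groupings gave at most 1 site. The short knockdown lists keep that count low, since 97.9 to 98.0% of their peaks lay in each mock list, so it says little about replicate differences. The 5 gained sites became 44 without knockdown replicate 1 and 39 without knockdown replicate 2. With lists of equal length 276 sites were lost and 164 gained.

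Ribosomal protein genes lost CP190 less often than other gene-end sites, with 35 of 71 sites lost (49.3% against 70.3%, odds ratio 0.411, 0.249 to 0.676, Fisher's exact test, two-sided, adjusted p = 0.00302). RpS14a (35.0 and 37.9), RpL17 (34.5 and 31.3) and RpS28a (21.5 and 39.9) were among the 27 retained. Within quintiles of peak strength the odds ratio was 0.462, with an interval that held 1 (Mantel-Haenszel, 0.209 to 1.02), so the call did not hold. With peaks of -log10 q of 10 or more it did not hold either (0.60, Fisher's exact test, adjusted p = 0.378). No other list passed. Respiratory chain genes lost 41 of 53 sites, proteasome genes 22 of 29, translation initiation factor genes 18 of 30 and replication licensing genes 9 of 13. The retained ones included ND-B8 (33.8 and 32.1), Prosbeta2R2 (19.5 and 24.9), eIF4G2 (30.2 and 29.1) and Orc4 (27.5 and 28.8). Heat shock genes lost 7 of 9, with Hsp110 lost (7.82 and 9.78), and cell cycle genes 11 of 16, with CycA lost (15.9 and 15.2) and stg retained (29.2 and 32.3). Insulator protein genes lost 8 of 10, with pita (17.5 and 23.3) and Ibf1 (12.2 and 11.1) lost and CTCF retained (24.3 and 22.9). Histone genes lost 1 of 4, His3.3A (7.77 and 6.80), and retained His2Av (16.8 and 19.2).

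M1BP kept most of its sites after CP190 knockdown, and kept them more often where CP190 had been bound. Of 3173 sites bound in both mock libraries of the second experiment 188 were lost (5.92%, 95% Wilson interval 5.16 to 6.80), 2805 were retained and 126 were gained. At CP190 sites 95 of 2753 were lost (3.45%, 2.83 to 4.20), against 93 of 420 away from CP190 (22.1%, 18.4 to 26.4). Lost gene-end sites without CP190 lay at CG14464 (2R, 4828967 to 4829531, 10.9 and 4.57), CG14931 (2L, 11788076 to 11788694, 7.30 and 6.84) and CG11836 (5.22 and 6.71). Those with CP190 lay at Argk2, an arginine kinase gene (3L, 9047202 to 9047713, 6.82 and 7.09), CG15742 (5.02 and 7.56), NT5E-2 (6.14 and 6.21), lov (6.71 and 5.16) and CG12477 (7.31 and 4.17). Retained sites included Cks30A, a cell cycle kinase subunit gene (44.3 and 51.4), the site between msl-2, a dosage compensation gene, and ND-PDSW (38.7 and 45.8), egh (36.9 and 45.9), Cpes (30.6 and 45.3) and HemK1 (37.3 and 37.6), all at CP190 sites. Gained sites lay at yps, a Y-box protein gene (6.55 and 4.56), Nin (4.76 and 5.36), CG11771 (5.34 and 4.11), Flacc (4.71 and 4.45) and Fign (5.31 and 3.73), which also overlapped CP190 sites.

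The odds ratio of M1BP loss at CP190 sites was 0.126 (0.0913 to 0.173, Fisher's exact test, two-sided, adjusted p = 4.74e-35). It was 0.212 with summits within 100 bp and 0.201 among gene-end sites. Lost sites had a median control rank of 13.9% and retained sites of 57.2%, and gene ends held 36.2% of lost against 87.7% of retained sites. Crossed groupings gave at most 75 sites. The lost count was 491 without mock replicate 2, and the gained count was 297 without mock replicate 1, 247 without knockdown replicate 1 and 328 without knockdown replicate 2.

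Of the gene-end M1BP sites at list genes, 1 of 63 was lost after CP190 knockdown at ribosomal protein genes and 0 of 43 at respiratory chain genes, against 2.60% and 2.62% of other gene-end sites, and neither list passed (adjusted p = 1 for both, Fisher's exact test). RpL37A (33.5 and 31.5), RpS15Aa (28.7 and 29.9), UQCR-C2 (30.9 and 40.5) and SdhB (27.7 and 35.6) were retained. No M1BP site was lost at proteasome (0 of 22), translation initiation factor (0 of 22), replication licensing (0 of 10), heat shock (0 of 4), insulator protein (0 of 9), histone (0 of 4) or cell cycle genes (0 of 14). Rpt4 (24.2 and 37.8), eIF3k (31.4 and 38.2), Mcm10 (20.0 and 25.0), Hsc70-4 (27.5 and 27.8), su(Hw) (20.8 and 20.5), mod(mdg4) (12.6 and 14.0), His4r (23.1 and 24.2) and Rbf (29.8 and 34.2) were among those retained. M1BP stayed at the Cp190 gene (5.04 and 4.80 in mock, 6.25 and 7.01 in knockdown).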

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

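The tests of how many gained sites rank within the control length were chosen after the results were seen, and the strength quintiles, fixed earlier as an alternative, were taken up as tests of an explanation after their results were seen. The readings of 4 values depart, also after they were seen, from the rules written for them: by those rules 2.08, 30.9% and 19.4% would argue against longer lists and 0.713 would speak for them.

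After M1BP knockdown the number of Su(Hw) peaks changed by 19.5% and that of Mod(mdg4) peaks by 56.6%, with each knockdown library above each mock library, while M1BP peaks went the opposite way in every library, by -39.7%, a difference between antibodies that was not tested. Of gained sites 30.9% (95% interval 27.2 to 34.9, 171 of 553) for Su(Hw) and 19.4% (16.3 to 22.9, 107 of 552) for Mod(mdg4) ranked within the length of the shortest mock list in both knockdown lists, against at most 4 and 25 sites in crossed groupings. Longer lists that reach weaker peaks stay open all the same for both, since 5 and 27 gained sites ranked within 75% of that length, and the others of these shares ranked in its last 25% in 1 or both lists, where small shifts in rank move sites across. The crossed count of Su(Hw) is also kept low, since 98.0 to 98.7% of its mock peaks lay in each knockdown list. Gains over losses at equal length, 2.08 (1.61 to 2.70) for Su(Hw) and 0.713 (0.582 to 0.874) for Mod(mdg4), decide nothing, since with fixed totals replicate agreement sets this ratio, and mirrored crossed groupings reached 2.29 and 2.57. Median fold was lower in Su(Hw) knockdown than mock lists (8.40 and 9.26 against 10.7 and 11.3). Their median -log10 q was higher (127 and 115 against 84.7 and 78.9). Mod(mdg4) knockdown lists had lower median fold (3.453 and 3.296 against 6.938 and 6.228). Their median -log10 q was lower too (12.4 and 10.04 against 18.8 and 19.9). At -log10 q of 10 or more they held 3094 and 2433 peaks against 1897 and 2409. Medians shift with list length, and folds are not scaled between libraries. Read depth and pull-down yield were not tested and stay open beside an effect of M1BP.

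CP190 loss after M1BP knockdown was more frequent at M1BP sites (odds ratio 3.79). Weaker CP190 peaks at M1BP sites, as split into quintiles, do not account for the whole of it, since the odds ratio within strength quintiles was 3.39 (2.66 to 4.32). Nor does unstable calling there, since sites at M1BP dropped out less often between the 2 mock lists (0.515, 0.432 to 0.614). Differences in strength inside the weakest quintile were not separated, and lost CP190 sites had a median control rank of 14.3%. Loss of M1BP at the same site, the explanation the design names, predicts more CP190 loss where M1BP was lost than where it was retained, and that odds ratio was 1.08 (0.756 to 1.54, with 55 lost and 553 kept against 108 lost and 1176 kept). This interval leaves the explanation open, because retained M1BP peaks may be reduced without leaving the list.

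M1BP loss after CP190 knockdown was less frequent at CP190 sites (odds ratio 0.126). Strength split into quintiles does not account for the whole of it, with 0.181 (0.13 to 0.253) within them. Differences in strength inside the weakest quintile were not separated, and lost M1BP sites had a median control rank of 13.9%. Unstable calling away from CP190 sites goes the same way but less far, with a dropout odds ratio of 0.313 (0.264 to 0.371) between the mock lists against 0.139 (0.12 to 0.161) from mock to knockdown under the replicate block, so it may hold a part. Among CP190 sites the odds ratio of M1BP loss where CP190 was lost against retained was 1.44 (0.855 to 2.52, with 67 lost and 1714 kept against 20 lost and 736 kept). This interval leaves open whether loss of CP190 adds to M1BP loss at the same site, an effect that would weaken this pattern and not produce it.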

How the results depend on the processing

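Chosen after the data were seen were the tests with gene ends, with arms alone, and all alternatives of the ribosomal protein list, the Woolf test, the named sites and the peak numbers. Of 260 alternatives over 54 results 195 kept direction and side of the threshold (tests), stayed within 1.5 times (counts of sites) or within 1 SD of the replicates (ratios of peak numbers), 6 were weaker, 1 stronger, 6 reversed and 52 moved. Of 39 alternatives of the loss tests 38 left the call as reported, the exception being Mod(mdg4) at gene ends (2.60). The replicate block, whose numbers the labels do not tie to shared cultures, gave odds ratios of 1.97 for CP190, 7.84 for Su(Hw), 2.65 for Mod(mdg4) and 0.139 for M1BP, and rank differences between replicates correlated across retained sites at 0.0103 to 0.139 between control and knockdown.

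Equal list length changed lost counts to 275 for M1BP after M1BP knockdown, 84 for Su(Hw), 223 for Mod(mdg4) and 276 for CP190 after CP190 knockdown. It changed gained counts to 203, 175, 159 and 164 in that order. Fixed totals pull both counts together by construction. Summits within 100 bp gave 70 gained M1BP sites after M1BP knockdown, 86 lost Su(Hw) sites and 52 gained CP190 sites after CP190 knockdown. Peaks of -log10 q of 10 or more gave 41 lost and 245 gained Mod(mdg4) sites, and that setting and arms alone each left 1 gained CP190 site after CP190 knockdown.

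Leaving out 1 library gave gained M1BP sites of 37 to 98 after M1BP knockdown, lost CP190 sites of 359 to 517 and gained ones of 464 to 616, lost Su(Hw) sites of 29 to 58 and gained ones of 678 to 1042, and lost Mod(mdg4) sites of 120 to 376 and gained ones of 585 to 2230. After CP190 knockdown it gave gained CP190 sites of 5 to 44, lost M1BP sites of 278 to 491 and gained ones of 182 to 328. The rule then asks 1 library fewer, which raises counts by construction. The largest departures came without knockdown replicate 2 for 98, 616, 1042, 2230 and 328, without knockdown replicate 1 for 517 and 44, without mock replicate 1 for 376, and without mock replicate 2 for 58 and 491.

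For Su(Hw) gained at M1BP sites the odds ratio reversed to 0.902 with summits, and for Mod(mdg4) it reversed to 1.62 with the stricter q and to 2.08 with equal length (Fisher's exact adjusted p = 0.0217, range 0.0217 to 1). The M1BP overlap with Su(Hw) reversed to 1.62-fold with summits, and that with Mod(mdg4) was 1.11-fold with the stricter q and 0.758 (odds ratio) among gene ends. The rank difference of Su(Hw) was -1.72 by -log10 p and 1.78 with summits. The ratio of CP190 to Mod(mdg4) odds ratios was 0.144 with the stricter q. The ribosomal protein odds ratio of CP190 loss was 0.462 within strata, 0.60 with the stricter q and 0 with equal length, none past the threshold. Summits lowered the smallest share between replicates to 68.2% for M1BP, 68.0% for CP190, 80.2% for Su(Hw) and 45.3% for Mod(mdg4). With the stricter q the ratio of peak numbers was 1.06 for CP190 after M1BP knockdown, 1.28 for Mod(mdg4) and 0.214 for CP190 after CP190 knockdown. In these cases the cause was not tested.

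The stricter q left 3 of 5 named gained M1BP sites in either knockdown, 0 of 1 lost Su(Hw) and 1 of 8 lost Mod(mdg4) sites in their class. Not run were the motif windows, the tests at transcription start sites, the Woolf test with summits, and the second mock set for Su(Hw) and Mod(mdg4). Among gene ends Su(Hw) gave no odds ratio, with 1 of 34 lost at M1BP sites and 0 of 469 elsewhere (Fisher's exact p = 0.0676). What read depth limits is unknown.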

Other observations

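All tests of this part were chosen after the results were seen. The reading of the coincidence of gains departs from its rule, by which 31.3-fold would argue against independent gains.

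CP190 sites differed by the proteins that shared them. M1BP sites were those of the mock set of each experiment. Su(Hw) and Mod(mdg4) sites were those of the first mock set for both experiments, since neither protein was mapped in the second. Where Su(Hw) and Mod(mdg4) were bound without M1BP, 6 of 2255 CP190 sites were lost after M1BP knockdown (0.266%), and where M1BP was the sole partner 175 of 1868 were (9.37%). Sites with none of the 3 lost 102 of 2342 (4.36%) in that knockdown. Sites with all 3 partners lost 0 of 97 after M1BP knockdown and 16 of 100 after CP190 knockdown (16.0%), while sites with Su(Hw) alone lost 17 of 502 (3.39%) after M1BP knockdown and 526 of 533 (98.7%) after CP190 knockdown. After CP190 knockdown sites with M1BP as the sole partner lost 1787 of 2643 (67.6%), those with Su(Hw) and Mod(mdg4) 1433 of 2289 (62.6%) and those with none of the 3 lost 1716 of 2119 (81.0%). These groups differed in peak strength, with median control ranks in the second experiment of 83.6% for all 3 partners, 65.9% for Su(Hw) and Mod(mdg4), 50% for M1BP alone, 34.9% for none and 19.8% for Su(Hw) alone. In the first experiment the ranks were 82.5%, 66.8%, 41.1%, 42.0% and 23.5% in that order.

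M1BP loss after its own knockdown took 609 of 1975 sites shared with CP190 (30.8%) and 285 of 551 others (51.7%), an odds ratio of 0.416 (0.342 to 0.507, Fisher's exact adjusted p = 1.77e-18). Within strength quintiles the odds ratio turned to 1.52 (1.2 to 1.93, Mantel-Haenszel). At Su(Hw) sites it was 0.535 (0.336 to 0.851) and at Mod(mdg4) sites 0.439 (0.281 to 0.687) within the same quintiles, and 1.01 and 0.834 without them. By chromosome arm, M1BP loss went from 29.7% on 3L to 38.8% on X, and chromosome 4 lost 7 of 11 sites.

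A hypothesis is that M1BP-bound sites resist loss of CP190 during CP190 knockdown. CP190 was lost at 1818 of 2782 such sites (65.3%) and at 3708 of 5006 others (74.1%), an odds ratio of 0.660 (0.596 to 0.731, Fisher's exact p = 7.64e-16). Stronger CP190 peaks at M1BP sites do not account for it, since within strength quintiles the odds ratio was 0.350 (0.298 to 0.412). Steadier calling at M1BP sites could account for it, since CP190 sites there dropped out less often between the 2 mock lists of that experiment, with no knockdown (0.340, 0.284 to 0.406), by more than from mock to knockdown (0.629, 0.585 to 0.677). The hypothesis therefore has no support beyond that in these lists.

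Gained sites coincided between antibodies. Of 553 gained Su(Hw) sites 56 overlapped a gained Mod(mdg4) site, 31.3-fold the mean of the circular shifts (1.79 sites, one-sided permutation p = 1e-04, the smallest the shifts can give). In mock cells 2422 of 4296 Su(Hw) sites (56.4%) overlapped a Mod(mdg4) site, so an excess over shifts, which ignore shared sites, does not decide whether the gains were independent. Gained CP190 sites overlapped 32 gained Su(Hw) sites (24.6-fold) and 26 of 509 gained Mod(mdg4) sites on the arms (26.3-fold). Mbs and CG11672 gained both Su(Hw) and Mod(mdg4), and CG32170 gained Su(Hw) and CP190.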
